A study of Danio rerio with 34 samples.

How the data were processed

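Ovary RNA of 34 female zebrafish was hybridised singly to 1-colour (Cy3) Agilent arrays carrying 43803 non-control spots, which hold 43603 probes, and 1417 control spots. Per the labels' protocols, the fish were held for 96 h in flowing water with 0 (control), 0.01, 0.1, 1, 10 or 100 µg/L bisphenol A (BPA) without a carrier solvent, in 3 zebrafish tanks per concentration, and total RNA was isolated with RNeasy columns and labelled with the Quick Amp kit. Per the submitters' processing notes, Agilent Feature Extraction 9.5 and R 2.10.1 were used, and per the file headers the extraction version was 9.5.1.1. Per the file headers the arrays came from 9 slides, and slide 1 (replicate E at 0.1 µg/L, replicate F at 10 µg/L and replicate F at 100 µg/L) was scanned on a later day and extracted with another protocol. That slide carried no control array. Grouping followed the concentration in the labels, with 6 control fish, 5 at 0.01, 5 at 0.1, and 6 at each of 1, 10 and 100 µg/L. Fish weight, gonad weight and plasma vitellogenin were taken from the labels, and the gonadosomatic index was gonad weight in percent of fish weight.

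The deposited scanner files held green-channel intensity per spot, and the processed signal of the extraction software, background-subtracted per the file headers, was used. Each array's processed signal was divided by its 75th percentile over non-control spots. Spots carrying an outlier flag were left out, 0.114 to 1.84% per array, and saturated spots were kept, 52 to 224 per array. A floor of 0.109 times the 75th percentile was set after scaling, and log2 was taken. The floor was the lowest scaled value well above background on an array, taken from the array where it was highest, and 23.1% of the kept values lay on it (15.7 to 30.9% per array). Spots of 1 probe were averaged (50 probes had more than 1 spot). Probes well above background on at least 5 of the 34 arrays were kept (25966), and 492 of these were left out because fewer than 3 unflagged arrays remained in a group, which left 25474 probes tested.

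The deposited series matrix of the authors held a value table on an unstated scale. Set against each array's scanner values, its columns followed log2 of the mean signal (Pearson r 0.997 to 1.00, median 1.00) more closely than log2 of the processed signal (0.924 to 0.977), so the deposited table was read as log2 without background subtraction. Its column medians ran from 5.92 to 6.32, and the authors' normalization stayed unknown. It served as an alternative only.

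Gene names were taken from the files' accession where the gene table of assembly GRCz12tu held it (16568 probes), from a current symbol (2035) or from an older synonym (1079), and the file's own name was kept for 23921 probes. That table was used for names alone. Chromosome positions are those of the probes in the scanner files (build danRer6, Zv8, per the file headers). A symbol was available for 13650 tested probes, or 9621 genes, and each gene was represented by its brightest probe. A probe that was not well above background on any array of a group has only a bound there. The bound set the mean log2 of the brighter group against the dimmer group's mean of, per array, the higher of the floor and the probe's own signal. It is strict only where the probe was well above background on every array of the brighter group.

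Probes were tested with group means and moderated t statistics of limma 3.58.1 (R 4.3.3, statmod 1.5.0, version 1.17.8 of data.table), two-sided, with all 34 arrays sharing 1 estimate of spread per probe and Benjamini-Hochberg adjustment over the 25474 probes at 0.05. The estimates were computed as weighted least squares per probe with flagged values left out, followed by limma's squeezeVar. Each concentration was set against control, the unweighted mean of the 5 exposed groups against control, and a straight line over the 6 concentrations scored in order gave the change per step. A moderated F test covered the 5 contrasts. The gonadosomatic index and plasma vitellogenin were each fitted as a covariate beside the groups. Slide was fitted as a fixed block beside each count of probes and each list test, and differences within slides that held both control and exposed arrays were averaged per slide. In a simulated copy of the 10 µg/L comparison with 50 probes changed at each size, 12.0%, 56.0%, 92.0% and 92.0% of the probes with a true log2 change of 0.5, 1, 2 and 3 were called, and 6 of the 132 calls fell on unchanged probes. The simulated noise was independent between probes and arrays, without slides or a floor. These rates therefore check the computation and need not hold for the real arrays.

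The 24 gene lists were written before the data were examined. They covered steroid synthesis, steroid and gonadotropin receptors, the egg envelope, oocyte and germ line, granulosa and theca, TGF-beta family signalling, ovulation and follicle remodelling, vitellogenin and oestrogen-responsive genes, testis and sperm, hepatocyte and plasma protein, exocrine pancreas, intestine, erythrocyte, leukocyte and immune, muscle, stroma, xenobiotic and oxidative stress, heat shock, cell cycle, DNA methylation and chromatin, cholesterol and lipoprotein uptake, apoptosis and atresia, ribosomal proteins, and oxidative phosphorylation. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison. Beside it stand camera with an estimated correlation, limma's fry, which tests a list against no change and not against other genes, and the number of members past 0.05 when adjusted over the list alone. A list shift was the median log2 change of its members.

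The genes named in the report followed a rule. Up to 10 higher and 10 lower genes past 0.05 were named, and where fewer than 5 passed, the 5 higher and 5 lower genes of smallest p were given as values. The members of smallest p were drawn from the 4 lowest of each described list. The genes esr1, esr2a, esr2b, ar, vtg1, cyp19a1a, star, cyp17a1, fshr and lhcgr were always to be named, and esr1 was not among the tested genes.

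Weight, gonadosomatic index and vitellogenin were compared with control by exact two-sided permutation of the difference in means over all 462 or 924 splits, adjusted over the 5 concentrations, and against the order of concentration by 100000 permutations. Similarity of the 5 concentrations was the Pearson r between their log2 changes over the 25474 probes, set beside 100 simulated draws of unchanged groups sharing the controls and 10 splits of the controls. Calls under random groupings used 100 splits of the arrays, the real one included.

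Alternatives were quantile and median scaling, the 75th percentile over probes well above background on every array, normexp background correction with an offset of 50, other floors and filters, the authors' table as deposited and centred, slide, tank, array position, replicate letter, tank number and gonadosomatic index in the fit, array weights, other variance moderation, a threshold of 0.10, fits on only the groups compared, other concentration scores, and fits leaving out slide 1, the 2 arrays of brightest spike-ins, or each array in turn. The log2 of the array's 75th percentile of intensity was added as a covariate after the data had been seen, as were the fits leaving out slide 1 and the spike-in arrays. The median log2 change at 10 µg/L moved with the scaling, from 0.01 with the 75th percentile to 0.12 with the median, 0.23 with normexp, -0.18 with the percentile over probes measured on every array and -0.27 with the authors' table.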

Results

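Transcript levels were measured in the ovaries of 34 adult female zebrafish after 96 h in water with bisphenol A (BPA), a plastic monomer that can bind oestrogen receptors. Each fish gave 1 array, with 6 controls, 5 fish at 0.01 µg/L, 5 at 0.1, and 6 at each of 1, 10 and 100 µg/L. The 75th percentile of intensity per array ran from 126.9 to 408.8 (median 231.6), 38.3 to 58.9% of the spots were well above background, and arrays of a group correlated at 0.932 to 0.983. The number of arrays limits the precision of every value below. Slide accounted for 0.888 and 0.857 of the variance of the first 2 principal components, so results are given with slide as a block too.

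Plasma vitellogenin, the yolk precursor that the liver makes under oestrogen, averaged 16.1 mg/ml (SD 3.41) in the 6 control females and 9.24 mg/ml (SD 3.84) in the 6 at 10 µg/L. The means were 11.8 (SD 4.74) at 0.01, 14.6 (SD 2.02) at 0.1, 14.2 (SD 2.86) at 1 and 13.9 (SD 4.96) at 100 µg/L. The comparison asked whether any concentration moved this protein away from control. At 10 µg/L the difference was -6.85 mg/ml, and 5 of 6 females lay below the lowest control value of 11.8. The exact two-sided permutation test gave p = 0.0108, or 0.0541 when adjusted over the 5 concentrations. The test treated females of the same tank as independent. Over tank means the difference was -4.88 mg/ml, with p = 0.3 by the exact two-sided permutation test. Comparing 3 tanks with 3 cannot give an exact p under 0.1, and the result lay above that limit. Over single females, the other 4 concentrations gave exact p from 0.117 to 0.411, where the smallest possible value was 0.00216.

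Ovary weight relative to body weight averaged 13.1% (SD 4.33) in control and 12.0, 9.73, 11.8, 15.0 and 10.1% from 0.01 to 100 µg/L, with exact p from 0.173 to 0.758. Body weight averaged 0.828 g (SD 0.257) in control and 0.590 to 0.742 g in the exposed groups, with exact p from 0.0866 to 0.517. Against the order of concentration over 34 fish, vitellogenin gave Pearson r = -0.239 (permutation p = 0.174) and Spearman rho = -0.232 (permutation p = 0.189). Without the 2 farthest fish its r was -0.236. The gonadosomatic index gave r = -0.0493 (p = 0.784), rho = -0.0322 (p = 0.855) and r = -0.0113 without 2 fish, all by permutation. Body weight gave r = -0.0825 (p = 0.651), rho = 0.0759 (p = 0.669) and r = -0.0383 in the same way by permutation. Adjusted over these 3 trends, p was 0.523 for vitellogenin and 0.784 for the other two.

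**Figure D1:**
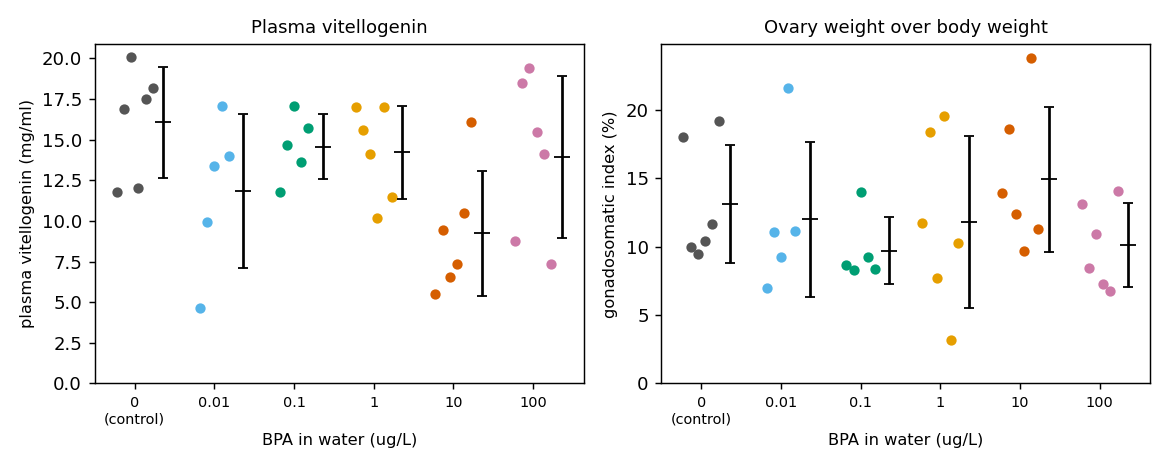
Plasma vitellogenin (mg/ml) and gonadosomatic index (% of body weight) by BPA concentration (µg/L), with 1 point per female and bars at the mean and SD of 5 or 6 females. The mean of vitellogenin was 9.24 mg/ml at 10 µg/L against 16.1 mg/ml in control.

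At 10 µg/L, acy1, the cytosolic aminoacylase that frees amino acids from their N-acetylated forms, rose 2.36-fold (log2 1.24, SE 0.23, adjusted p = 0.0381). A COMM domain gene of copper and vesicle traffic, commd2, rose 2.17-fold (log2 1.12, SE 0.20, adjusted p = 0.0381). The sulfate transporter slc26a2, which supplies sulfate for proteoglycans, fell 2.15-fold (log2 -1.11, SE 0.19, adjusted p = 0.0237). The mitochondrial gene nipsnap3a rose 1.88-fold (log2 0.91, SE 0.13, adjusted p = 0.00207). The expressed tag EH602155, which carries no gene name, rose 3.33-fold (log2 1.73, SE 0.32, adjusted p = 0.0381). All 6 females at this concentration lay on the same side of the control mean for each of the 5. The probes of nipsnap3a and EH602155 lie outside the naming rule and were added after the values were seen. The nipsnap3a probe is not the brightest of its gene, and the 1 other tested probe was not called, though of the same sign. The other tested probes of acy1 (1) and commd2 (2) also had the same sign and were not called. EH602155 was well above background on 4 of 6 control arrays. Its values in control replicates A, C, E and F nevertheless lay on the floor (log2 -3.20). The size of its rise therefore depends on where the floor was set. In the scanner files (build danRer6), the probe of acy1 lay on chromosome 22 from 38283414 to 38283473 and that of commd2 on chromosome 22 from 41076613 to 41076672. The probes of slc26a2 lay on chromosome 14 from 26932065 to 26932124, of nipsnap3a on chromosome 14 from 6767951 to 6768010, and of EH602155 on chromosome 13 from 25457459 to 25457518.

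The comparison asked how many of 25474 probes differed between 6 exposed and 6 control females. Limma called 5 of them (4 higher, 1 lower), with 5223 at unadjusted p under 0.05 (3603 higher, 1620 lower). The 6 females of each group shared 3 tanks, and 2 probes were called with tank as a random block and 1 with tank number as a fixed block. With slide as a fixed block the count was 0, with 4123 at unadjusted p under 0.05. The log2 values under that block kept their sign, with acy1 at 1.29 (adjusted p = 0.101), commd2 at 1.02 (0.199), slc26a2 at -1.09 (0.111), nipsnap3a at 0.85 (0.101) and EH602155 at 1.40 (0.199). Within the 3 slides that held both groups, acy1 differed by 0.73 to 1.75 and commd2 by 0.80 to 1.20. The same slides gave slc26a2 differences of -1.54 to -0.37, with nipsnap3a by 0.66 to 1.21 and EH602155 by 0.24 to 2.38. The moderated F test over all concentrations called acy1 and nipsnap3a, with 2330 probes at unadjusted p under 0.05.

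**Figure D2:**
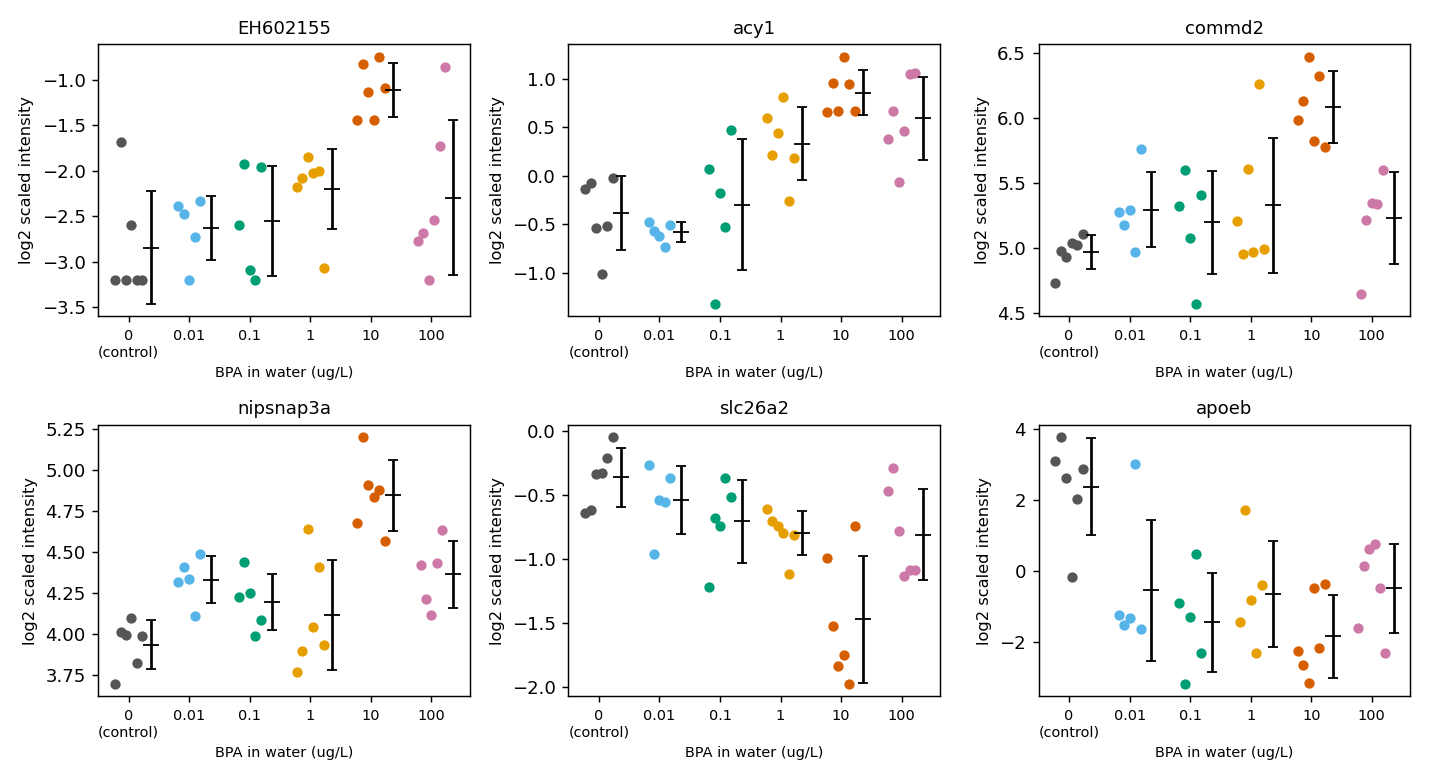
Level of 6 genes (log2 relative to each array's 75th percentile) by BPA concentration (µg/L), with 1 point per female and bars at the mean and SD. At 10 µg/L acy1 rose by log2 1.24 and slc26a2 fell by 1.11, while apoeb differed by -4.22 without passing the test.

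Apolipoprotein E, encoded by apoeb and made by macrophages among other cells for lipid transport, was 18.6-fold lower at 10 µg/L (log2 -4.22, SE 0.82, 6 of 6 females lower), with adjusted p = 0.0547 over all probes. Its probe was well above background on 3 of 6 exposed arrays and on all 6 controls. The slide-block value was -4.38 (adjusted p = 0.199), and the 3 shared slides gave -6.05 to -2.51. Next in order were aimp1a, a scaffold of aminoacyl-tRNA synthetases, at 1.46 (SE 0.29, adjusted p = 0.0588). After it came the splicing factor srsf7b at 1.61 (SE 0.33, 0.0723) and the complex I subunit ndufs5 at 0.85 (SE 0.17, 0.0723). The polarity genes pals1b and prickle2b were at -0.84 (SE 0.19) and -1.37 (SE 0.33), and arfip2b of Golgi traffic at -0.81 (SE 0.18).

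Whether the 5 calls belonged to 10 µg/L stayed open. These probes were picked for their distance from control at that concentration, which by itself sets them apart from the other groups. Adjusted over all probes, 1 of the 20 differences between 10 µg/L and another concentration passed 0.05, acy1 against 0.01 µg/L (1.44, SE 0.24, adjusted p = 0.0282), and the others had adjusted p from 0.0625 to 0.738. The difference of acy1 from 100 µg/L was 0.26 (SE 0.23). At 100 µg/L acy1 was 1.97-fold above control (log2 0.98, SE 0.23, 6 of 6 females higher).

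Transcripts of ribosomal proteins, which build the translation machinery stored in the egg, were higher as a group by camera at 10 µg/L, with a median log2 change of 0.63 and 74 of 75 members above 0. With an estimated correlation this list had adjusted p = 0.424, and its mean was higher on dimmer arrays, which this group had, so the difference is not settled as an effect of BPA. Adjusted over the list alone 56 members rose, 0 fell and 19 did not pass, and over all probes 0 passed. Among them rps21 rose by 1.07 (SE 0.27), rps4x by 0.89 (SE 0.26), rpl30 by 1.24 (SE 0.36) and rpl3 by 0.80 (SE 0.22). The spot of rpl3 was saturated on 1 of 6 control and 3 of 6 exposed arrays. Oxidative phosphorylation genes, the mitochondrial energy chain, had a median of 0.60 with the same 2 limits (adjusted p = 0.424 with an estimated correlation), and 48 of 73 members were past the list-alone adjustment. They included ndufs5, ndufb8 at 1.05 (SE 0.22), the assembly factor ndufaf5 at 1.73 (SE 0.39) and ndufb11 at 0.95 (SE 0.21). Egg envelope genes, whose proteins form the zona pellucida, had a median of 0.57 (adjusted p = 0.424 with an estimated correlation) with 15 of 15 above 0 and 4 past the list-alone adjustment. These were zpd at 1.34 (SE 0.47), zp2l1 at 0.59 (SE 0.22), zp3d.1 at 0.57 (SE 0.17) and zp3, whose spots were saturated on all 12 arrays. A saturated spot can rise on dimmer arrays through the scaling alone, so the pass of zp3 is no evidence of a change. The egg envelope list was not tested against array intensity, so the limit from dimmer arrays cannot be set aside for it.

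The list test asked whether members of a list changed more than other genes. Camera gave adjusted p = 1.79e-20 for ribosomal proteins, 2.53e-18 for oxidative phosphorylation and 5.54e-05 for the egg envelope, each with adjusted p = 0.424 with an estimated correlation. By fry, which tests a list against no change and not against other genes, the values were 0.0179, 0.00717 and 0.0113. With slide as a block camera gave 1.69e-14, 1.69e-14 and 0.00646, with medians of 0.49, 0.45 and 0.30. The list means within the 3 shared slides ran from 0.49 to 0.70, 0.52 to 0.61 and 0.41 to 0.71. The arrays at 10 µg/L were dimmer than the controls, with a mean 75th percentile of 173 (SD 42.0) against 245 (SD 27.8). The difference was -71.9 (exact two-sided permutation p = 0.00866, adjusted 0.0433).

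Within groups, the list mean of ribosomal proteins followed array intensity over 34 arrays with r = -0.733 (permutation p = 2.00e-05, adjusted over 2 lists 4.00e-05) and rho = -0.755 (permutation p = 1.00e-05). Without the 2 farthest arrays r was -0.687. For oxidative phosphorylation r was -0.698 (permutation p = 8.00e-05, adjusted 8.00e-05), rho -0.672 (permutation p = 1.10e-04) and r -0.610 without 2 arrays. With log2 of intensity as a covariate the medians were 0.31 and 0.35 at 10 µg/L, and with quantile scaling 0.12 and 0.22. The egg envelope median also fell with quantile scaling, and camera no longer called that list. No correlation with intensity was computed for it. At 100 µg/L its list mean was 0.67 and 0.55 on the dimmest arrays (replicates F and E). On the brightest arrays of that group (B and C) it was -0.60 and -0.35.

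**Figure D3:**
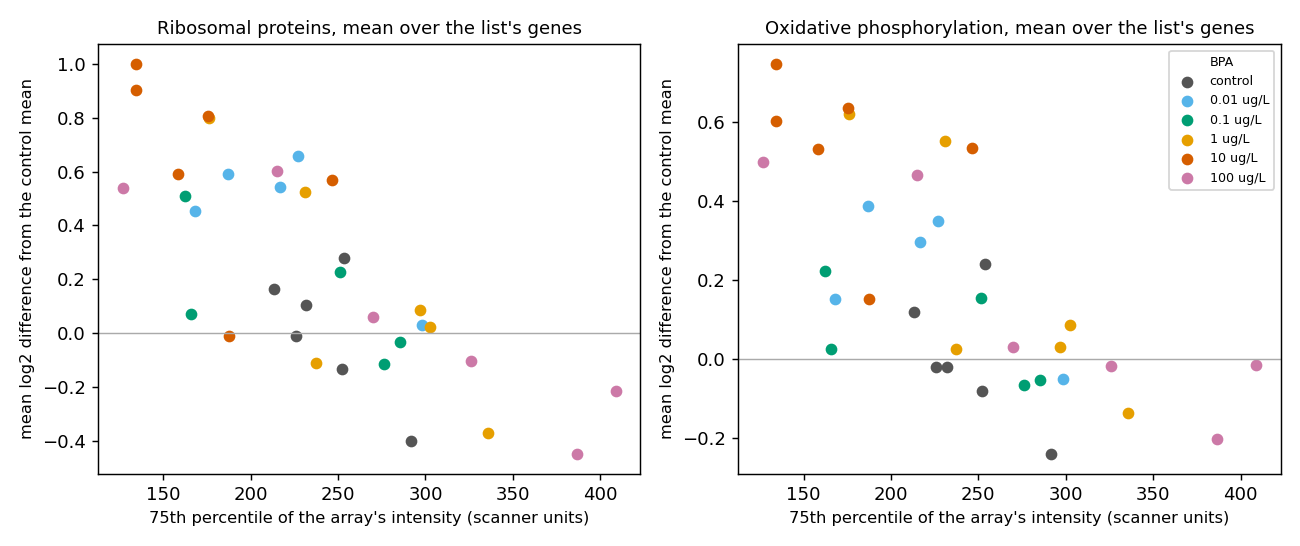
List mean of ribosomal protein and oxidative phosphorylation genes (log2 difference from the control mean) against the array's 75th percentile of intensity, with 1 point per female coloured by BPA concentration. Dimmer arrays had higher list means, with r = -0.733 and -0.698 within groups.

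Leukocyte and immune genes fell as a group by the camera test at 10 µg/L (mean log2 change -0.29, median -0.08, 28 of 43 members below 0, adjusted p = 0.0253). It had adjusted p = 0.424 with an estimated correlation and 0.173 by fry. Adjusted over the list alone 3 members fell, 0 rose and 40 did not pass. The granulin gene grna.2 was at -3.22 (SE 0.85, well above background on 2 of 6 exposed arrays), complement c1qc at -1.60 (SE 0.46, 3 of 6) and the lysosomal cathepsin ctss2.1 at -0.59 (SE 0.18). Complement c1qb, not well above background on any array at 10 µg/L, was at least 1.81-fold lower. The slide block gave adjusted p = 0.105 and a median of 0.08, and the 3 shared slides gave list means of -0.45 to 0.24.

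The remaining 20 lists were not called at 10 µg/L. Their median log2 changes were 0.20 for cell cycle (adjusted p = 0.0578; 7 higher and 2 lower over the list alone), 0.19 for DNA methylation and chromatin (camera 0.145, fry 0.0113) and 0.18 for apoptosis and atresia (4 and 1). Oocyte and germ line genes had 0.21 (3 and 1), heat shock 0.18 and muscle 0.14 (3 and 0). Others were 0.12 for xenobiotic and oxidative stress (1 and 0), 0.07 for granulosa and theca and 0.04 for steroid synthesis (1 and 0). Further medians were 0.04 for TGF-beta family signalling, 0.03 for ovulation (1 and 0; mean -0.12), 0.00 for hepatocyte and plasma protein (0 and 1; mean -0.06) and -0.01 for cholesterol and lipoprotein uptake (2 and 3). Erythrocyte genes had -0.03, intestine -0.05 and vitellogenin and oestrogen-responsive genes -0.07 (mean 0.06). The last medians were -0.07 for testis and sperm (2 and 0; mean 0.23), -0.08 for exocrine pancreas, -0.11 for steroid and gonadotropin receptors (mean 0.01) and -0.18 for stroma.

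Steroid pathway and receptor genes were asked about directly, since BPA can act through oestrogen receptors. By limma 0 of the 9 measured passed in any comparison. At 10 µg/L the log2 values were -0.36 (SE 0.22) for ar, -0.45 (SE 0.28) for esr2a, -0.62 (SE 0.63) for esr2b and -0.39 (SE 0.30) for cyp17a1. They were 0.03 (SE 0.44) for the ovarian aromatase cyp19a1a, 0.34 (SE 0.34) for fshr, -0.39 (SE 0.69) for lhcgr and 0.85 (SE 0.83) for vtg1. The probe of star, the cholesterol carrier of steroid synthesis, was well above background on 1 control array and on 0 of the 6 arrays at that concentration. The smallest unadjusted p by limma among the 9 was 0.0524, for cyp19a1a at 0.1 µg/L (0.93, SE 0.46), beside 0.93 at 0.01 µg/L (0.0541) and 0.83 at 1 µg/L (SE 0.44, 0.0690). With slide as a block the limma values of cyp19a1a at 0.01, 0.1 and 1 µg/L were 0.80, 0.90 and 0.76 (SE 0.36, 0.37 and 0.34, unadjusted 0.0364, 0.0241 and 0.0346, each adjusted 1). The block also gave -0.52 at 10 µg/L for ar (SE 0.22, unadjusted 0.0257, adjusted 0.255) and turned lhcgr to 0.51 (SE 0.39). The smallest adjusted p of the 9 under the block was that of ar.

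At 0.01 µg/L the largest differences by p were tekt4, a ciliary tektin, at least 6.36-fold higher in 5 females (not well above background in control), and the bHLH gene usf1l at 1.85 (SE 0.48). Next were afap1l1b of the actin skeleton at 1.57 (SE 0.39) and zbtb16a at 1.42 (SE 0.36). Lower were the alpha-catenin ctnna2 at -1.30 (SE 0.31) and the crystallin crygn1, 8.17-fold lower by the bound and not well above background at 0.01 µg/L. The bound of crygn1 is not strict, since its probe was well above background on 5 of 6 control arrays. The comparison with control called 0 probes by limma (1115 at unadjusted p under 0.05; slide block 0 and 946), and the smallest adjusted p among these genes was 0.696. Camera called 4 lists. Ribosomal proteins had a median of 0.46 with 74 of 75 above 0 (adjusted p = 1.36e-25, adjusted p = 0.534 with an estimated correlation, slide block 3.90e-06). Oxidative phosphorylation had 0.27 with 61 of 73 above 0 (6.12e-09, adjusted p = 0.618 with an estimated correlation, slide block 0.423). Cell cycle genes had 0.18 with 33 of 43 above 0 (0.00148), and egg envelope genes 0.26 with 13 of 15 (0.00443), both with adjusted p = 0.618 with an estimated correlation and 0.75 under the slide block. No member passed over the list alone, and examples were rps23 at 0.71 (SE 0.25), ndufaf5 at 1.25 (SE 0.41), aurka at 0.25 (SE 0.11) and zpd at 1.51 (SE 0.47).

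At 0.1 µg/L the prostaglandin synthase ptgs1 was at 1.62 (SE 0.41, 5 of 5 females), kif20a of cell division at 0.91 (SE 0.25) and srsf7b at 1.15 (SE 0.33). Lower values were apoeb at -3.82 (SE 0.86, 14.1-fold), the fatty acid carrier fabp4a at -3.24 (SE 0.86, 9.46-fold), coagulation factor f5 at -2.45 (SE 0.58) and the amino acid transporter slc7a7 at -1.34 (SE 0.36). Probes of apoeb, fabp4a and f5 were well above background on 4 of 5 exposed arrays and that of slc7a7 on 1 of 5, and ptgs1 on 4 of 6 control arrays. Of the probes, limma called 0 against control (591 at unadjusted p under 0.05; slide block 0 and 795). Camera called 3 lists. Ribosomal proteins had a median of 0.11 with 67 of 75 above 0 (adjusted p = 0.00117, adjusted p = 0.861 with an estimated correlation, slide block 0.474). Egg envelope genes had 0.24 with 15 of 15 (0.00706, adjusted p = 0.712 with an estimated correlation, slide block 0.474). Leukocyte and immune genes had -0.22 with 32 of 43 below 0 (0.00130, adjusted p = 0.305 with an estimated correlation, slide block 0.169). The matrix protease mmp13a was at -2.67 (SE 0.79), grna.2 at -2.35 (SE 0.90) and the actin bundler lcp1 at -1.24 (SE 0.48), each lower in 5 of 5 females and well above background on 3, 3 and 2 of the 5 exposed arrays. The leukocyte list means were -0.55 and -0.05 within the 2 slides shared with control.

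At 1 µg/L the GTPase rab18b was at 0.70 (SE 0.17), kif2a of the spindle at 0.90 (SE 0.22), the calcium sensor tescb at 1.65 (SE 0.41) and usf1l at 1.71 (SE 0.46), each higher in 6 of 6 females. Lower values were apoeb at -3.02 (SE 0.86, 5 of 5), eral1 of the mitochondrial ribosome at -1.18 (SE 0.35) and scinlb, 1.61-fold lower by the bound (not well above background at 1 µg/L). The bound of scinlb is not strict, since its probe was well above background on 4 of 6 control arrays. Limma called 0 probes (846 at unadjusted p under 0.05; slide block 0 and 768). Camera called oxidative phosphorylation (median 0.18, 59 of 73 above 0, adjusted p = 1.63e-05, slide block 0.00573) and ribosomal proteins (0.16, 56 of 75, 0.00937, slide block 0.773). It also called hepatocyte and plasma protein genes (0.63, 27 of 30, 1.63e-05, slide block 8.93e-08), and all 3 lists had adjusted p = 0.992 with an estimated correlation. The hepatocyte list mean was 3.54 in replicate B against at most 0.61 in the other 5 females, and that array also had an intestine list mean of 0.78 (others at most 0.41). Without it the hepatocyte median was 0.06 (adjusted p = 0.932). Members included rbp4 at 1.99 (SE 1.06), c9 at 1.29 (SE 0.68) and sdhc of complex II at 0.73 (SE 0.30). Over the hepatocyte list alone only apoeb passed, as lower (0.0424).

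At 100 µg/L acy1 led the higher genes, with ptgs1 at 1.45 (SE 0.39, 6 of 6 females), itpa of nucleotide repair at 0.91 (SE 0.26) and prickle1a at 0.44 (SE 0.12). Lower values were slc7a7 at -1.35 (SE 0.34), the stress factor ddit3 at -0.90 (SE 0.26) and apoeb at -2.86 (SE 0.82, 6 of 6). The probes of slc7a7 and ddit3 were well above background on 5 of 6 control arrays and on 2 and 4 of 6 exposed arrays. Limma called 0 probes (648 at unadjusted p under 0.05; slide block 0 and 1236). Camera called oxidative phosphorylation (median 0.12, 56 of 73 above 0, adjusted p = 0.00649, slide block 7.65e-05) and hepatocyte and plasma protein genes (0.38, 25 of 30, 0.0325, slide block 0.0878). It also called leukocyte and immune genes (-0.07, mean -0.19, 27 of 43 below 0, 0.0397, slide block 0.266), and all 3 lists had adjusted p = 0.909 with an estimated correlation. The hepatocyte list mean was 2.14 and 1.13 in replicates C and E against at most 0.02 in the other 4 females, the intestine list mean was 0.86 and 0.44 in these 2 arrays, and leaving out 1 array lowered the median to as little as 0.16. Over the hepatocyte list alone apoeb passed as lower (0.0460). Other values were 2.22 (SE 1.39) for the liver fatty acid carrier fabp10a, 1.43 (SE 0.68) for c9, -2.72 (SE 0.85) for grna.2 (3 of 6 exposed arrays well above background) and 0.49 (SE 0.23) for ndufb8.

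In the mean of all 5 exposed groups, ptgs1, the enzyme that starts prostaglandin synthesis, was 2.74-fold higher (log2 1.46, SE 0.30) in 28 of 28 exposed females, and was well above background on 4 of 6 control arrays. Lower were apoeb at -3.37 (SE 0.64, 10.3-fold, 26 of 27 females), slc7a7 at -1.19 (SE 0.27, 26 of 28) and fabp4a at -2.56 (SE 0.64, 26 of 28). These 3 were well above background on 24, 7 and 26 exposed arrays. The comparison of 28 exposed with 6 control females asked for changes shared by all concentrations. Limma called 0 probes (1423 at unadjusted p under 0.05; slide block 0 and 1069). The adjusted p was 0.104 for apoeb, 0.154 for ptgs1, 0.278 for slc7a7 and 0.578 for fabp4a. Adjusted over the hepatocyte list alone, apoeb passed at 3.68e-04. Camera called ribosomal proteins (median 0.29, 72 of 75 above 0, adjusted p = 2.17e-14, slide block 3.09e-06) and egg envelope genes (0.24, 15 of 15, 0.00554, slide block 0.468), both with adjusted p = 0.676 with an estimated correlation. It also called oxidative phosphorylation (0.25, 66 of 73, 4.64e-12, slide block 2.71e-06) and leukocyte and immune genes (-0.12, mean -0.21, 30 of 43 below 0, 0.0325, slide block 0.287), both with adjusted p = 0.615 with an estimated correlation. Examples were ndufa10 at 0.57 (SE 0.18), rpl38 at 0.77 (SE 0.29), zpd at 1.03 (SE 0.35) and grna.2 at -2.19 (SE 0.67).

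Over the order of concentration acy1 had a fitted slope of 0.28 per step (SE 0.039, adjusted p = 0.00150), or 0.26 with slide as a block (adjusted p = 0.0196). It did not rise at every step. Its level at 10 µg/L exceeded control by 1.24, and 0.01, 0.1, 1 and 100 µg/L by 1.44, 1.15, 0.52 and 0.26. The caspase gene casp2 was at 0.22 per step (SE 0.050), ptprfb at 0.18 (SE 0.043), hic1 at -0.23 (SE 0.055) and slc26a2 at -0.15 (SE 0.032), with adjusted p from 0.235 to 0.244. The trend asked for a steady change from 0 to 100 µg/L. Limma called 1 probe of 25474 with and without the slide block (2940 and 3972 at unadjusted p under 0.05). Oxidative phosphorylation was the 1 list called (median 0.05 per step, 61 of 73 above 0, adjusted p = 3.97e-07, adjusted p = 0.980 with an estimated correlation, slide block 2.46e-10). Its member ndufb8, at 0.16 (SE 0.039), was past the list-alone adjustment (0.0317).

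Changes at the 5 concentrations resembled one another about as much as the shared controls alone give. The median Pearson r over 10 pairs of concentrations was 0.514, simulated unchanged groups gave 0.480, and 40 of 100 draws were as high. With separate controls on each side r was 0.109. The median covariance was 0.0653 against 0.0525 simulated, with 24 of 100 draws as high.

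Among females of the same group, ovaries of higher gonadosomatic index had more transcript of the leukocyte genes mmp13a (0.16 per percent, SE 0.044), lcp1 (0.093, SE 0.027) and arpc1b (0.090, SE 0.027), which passed over the leukocyte list alone (each 0.0309). The fit asked which transcripts followed ovary size. Limma called 0 of 25474 probes (1925 at unadjusted p under 0.05). With slide as a block 1 probe without a gene name was called (0.11 per percent, SE 0.016, adjusted p = 0.0374), with 1991 at unadjusted p under 0.05. Camera called ribosomal proteins (median -0.02, adjusted p = 6.06e-07, slide block 0.0276), oxidative phosphorylation (-0.02, 6.06e-07, slide block 0.0173) and hepatocyte and plasma protein genes (0.05, 1.60e-05, slide block 4.30e-04). It also called leukocyte and immune genes (0.00, 0.0167, slide block 0.119) and heat shock genes (-0.01, 0.0167, slide block 0.151), and all 5 had adjusted p = 0.634 with an estimated correlation. Plasma vitellogenin gave 0 called probes (1816 at unadjusted p under 0.05; slide block 0 and 2737). Camera called ribosomal proteins (-0.03 per mg/ml, 1.65e-11, slide block 1.88e-21), oxidative phosphorylation (-0.02, 3.31e-08, slide block 4.91e-12) and oocyte and germ line genes (-0.03, 0.00223, slide block 0.0541), each with adjusted p = 0.503 with an estimated correlation. Examples were the oocyte growth factor gdf9 at -0.046 (SE 0.015) and rps8b at -0.072 (SE 0.022).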

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

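The slide, ovary size, single-probe, inherited-state and liver tests and the splits without replicate F were chosen after the results had been seen, and the others before. The tests about replicate F could be framed only once its removal had been seen to raise the calls. Leaving out replicate F at 10 µg/L raised the calls there from 5 to 2583 (1902 higher, 681 lower), with all 5 kept. That array was singled out because its absence gave the most calls of the 34 arrays left out in turn. Replicate F itself differed from control in the direction of the call for 1270 of the 2583 probes. Its median difference in that direction was 0, against 0.83 in the other 5 females. Its plasma vitellogenin was 16.1 mg/ml, against 5.49 to 10.5 in the others, and it was the only female of its group from tank 3. A weaker response of this fish (slope on the other 5 of 0.268, against 0.294 to 1.17 for the other females), its tank and the separate handling of slide 1 (mean r of 0.156 with the other 2 arrays of that slide, at 0.406 and -0.0950) could not be told apart. The slope of replicate F, below the lowest of the other 5, met the rule written for a weaker response. A margin of the SD of those 5 slopes, absent from that rule, was then required and was not reached. The processed signal of slide 1 differed in kind, with 0% of non-control spots negative on each of its arrays, against 8.36 to 24.9% on the other slides. Flagged spots made up 0.114 to 0.153% there, against 0.628 to 1.84%. Array intensity may hold part of it, since over the 22 arrays of the other groups the score along the 10 µg/L difference followed intensity at r = -0.746 (permutation p = 3.00e-04; rho = -0.702, permutation p = 0.00109; r = -0.596 without the 2 farthest arrays).

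Ribosomal protein and oxidative phosphorylation transcripts were higher at 10 µg/L, where the arrays were dimmer. Bright probes rose there too, with a median of 0.32 in the brightest of 4 equal sets of probes against -0.02, -0.16 and -0.00 in the others. Random lists matched on brightness had medians of 0.47 and 0.33 (95% of them 0.41 to 0.53 and 0.24 to 0.42), and both real lists lay above 100% of the draws. The draws took unrelated genes, while members of a list can move together, so the spread of the draws was likely too narrow. Brightness as the whole cause is thus not excluded. With slide as a block the lower list median was 0.448, and with gonadosomatic index as a covariate it was 0.613. Neither adjustment alone removed the difference. Medians of 0.31 and 0.35 remained with array intensity as a covariate, and the data do not settle how much of the rest came from dim arrays.

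Lower apoeb in the exposed females reached -4.22 at 10 µg/L. Its probes moved together over fish (lowest r 0.793), which excludes a sequence variant under a single probe. The values of the fish had a largest gap of 0.943 with 26 fish below and 7 above, too small to tell an inherited on or off state from a graded one. Fewer phagocytes could not be told from a change within cells. The mean of 24 phagocyte markers followed apoeb within groups at r = 0.231 (permutation p = 0.186; rho = 0.214, permutation p = 0.249; r = 0.185 without the 2 farthest fish), and 16 of the markers lay lower in exposed fish with a median of -0.06 (camera p = 0.414 with an estimated correlation). Several markers, such as csf1ra and mpeg1.2 (mean log2 -3.02 and -3.16), lay near the floor and could hardly show a fall.

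Random splits of the arrays into groups of the same sizes gave as many called probes as the real grouping in 2 of the 100 splits at 10 µg/L (real 5, highest other 1901). Without replicate F the count was 1 of the 100 splits (real 2583, highest other 1130), which excludes nothing, since that array was picked for the most calls and the other splits had no such choice. With 0 real calls, 100 of the 100 splits were as high at 0.01 (highest other 2), 0.1 (1), 1 (11) and 100 µg/L (122) and for the mean of the exposed groups (1911). The trend gave 7 of the 100 splits (real 1, highest other 613) and the F test 12 of the 100 splits (real 2, highest other 1434). Splits with as many as 1901 calls point to a structure among the arrays. The splits ignored slide, and arrays of the same slide had deviations from their groups correlated at 0.262, but what gave those calls was not tested and exposure is not excluded as part of it. Called lists gave 30 of the 100 splits at 0.01 (real 4, highest other 7), 39 at 0.1 (real 3, highest other 12), 69 at 1 (real 3, highest other 9), 26 at 10 (real 4, highest other 7) and 52 at 100 µg/L (real 3, highest other 8). They gave 37 for the mean of the exposed groups (real 4, highest other 9) and 87 for the trend (real 1, highest other 8), so the number of called lists was no larger than random groupings give.

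A value far from the rest of its group was found 8 times in 102 groups, where chance alone gives about 1 in 20. Replicate D at 0.01 µg/L had a gonadosomatic index of 21.7 (others 6.95 to 11.1), a body weight of 0.780 g (others 0.610 to 0.650) and an apoeb level of 3.01 (others -1.63 to -1.26). Replicate C at 0.1 µg/L had a gonadosomatic index of 14.0 (others 8.29 to 9.26). The hepatocyte list mean was 0.90 in replicate A at 0.1 µg/L (others -0.54 to -0.26) and 3.54 in replicate B at 1 µg/L (others -0.16 to 0.61). The oxidative phosphorylation mean was 0.15 in replicate F at 10 µg/L (others 0.53 to 0.75), and EH602155 was -3.07 in replicate F at 1 µg/L (others -2.17 to -1.85). Spike-in signal lay above the control range of 9.92 to 10.5 in 5 arrays, namely replicates B (11.6) and C (11.4) at 1 µg/L and B (10.7), C (10.8) and D (10.8) at 100 µg/L. It was lower than control by 0.53 at 0.01, 0.35 at 0.1 and 0.59 at 10 µg/L on average (exact two-sided permutation p = 0.0260, 0.0130 and 0.0303, each adjusted 0.0505).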

How the results depend on the processing

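Counts of called probes at 10 µg/L depended strongly on the processing, and the cause was not tested. Against 5 in the original fit, 0 were called with quantile scaling, median scaling, normexp, slide as a fixed block, and quantile scaling with slide as a fixed block. With tank as a random block or no filter on dim probes 2 were called, with array position 3, with tank number 1, and with the percentile over probes measured on every array 1 (lower). Higher counts came from slide as a random block (24), gonadosomatic index as a covariate (22), other variance moderation (10), fits on only the groups compared (11), a threshold of 0.10 (1562) and array weights (6125). The authors' table gave 5582 (73 higher, 5509 lower) and, with its columns centred, 773 (149 higher, 624 lower). Without slide 1 there were 2754, or 1323 with the slide block, 1097 (468 higher, 629 lower) with quantile scaling and 2677 (458 higher, 2219 lower) with the other percentile. Without the 2 arrays of brightest spike-ins there were 12. With array intensity as a covariate 1 was called, and 0 when slide 1 was left out too. The larger counts may have followed array intensity, but lost calls alone do not show it. In these fits apoeb stayed at -3.67 and -4.23 (limma adjusted p = 0.613 and 0.203), while the covariate lowered the ribosomal protein and oxidative phosphorylation medians.

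The probes called at 10 µg/L and apoeb kept their sign in every setting, while their calls did not hold in all. The settings refit the same arrays on genes picked for their result in the original fit, so this agreement in sign is no independent support. Over other processing settings nipsnap3a passed in 20 of 27 (log2 0.40 to 1.11), slc26a2 in 18 of 27 (-1.63 to -0.45), commd2 in 16 of 27 (0.65 to 1.32), acy1 in 14 of 27 (0.58 to 1.44) and EH602155 in 12 of 26 (0.61 to 1.95), with the same sign throughout. Leaving out 1 array at a time, they passed in 34, 28, 24, 21 and 23 of 34 fits. The trend of acy1 passed in 22 of 27 settings (0.19 to 0.34) and in 34 of 34 fits, and apoeb at 10 µg/L passed in 11 of 26 settings (-4.90 to -2.59) and in 10 of 34 fits.

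Other counts moved as follows. The F test, with 2 calls, gave 0 with median scaling, normexp, no filter, slide or tank or array position or tank number as a block, the other percentile (with and without slide 1), a lower floor, intensity as a covariate, quantile scaling with slide, and slide without slide 1. It gave 1 with quantile scaling, a filter on all arrays, other moderation, the arrays of brightest spike-ins left out, and intensity without slide 1. It gave 4 with slide as a random block, 5 with the centred table, 8 with quantile scaling without slide 1, 17 without slide 1, 2079 with array weights and 6737 with the authors' table. The trend, with 1 call, gave 0 with median scaling, normexp, the other percentile (with and without slide 1), log10 concentration over exposed fish and concentration itself. It gave 2 with gonadosomatic index or intensity as a covariate, 7 with array weights, 8 with the centred table, 29 with the authors' table and 160 with intensity without slide 1. The mean of the exposed groups, with 0 calls, gave 1 with normexp and with the centred table, 2 with the authors' table, 3 with other moderation, 7 without the arrays of brightest spike-ins and 121 with array weights. The comparison at 0.01 µg/L, with 0 calls, gave 1 without those arrays, 16 on only the groups compared and 74 with array weights. At 0.1 µg/L array weights gave 7, and at 100 µg/L the fit on only the groups compared gave 1. Gonadosomatic index, with 0 calls, gave 1 with a filter on all arrays or the slide block, 2 with that block without slide 1, 4 with the other percentile (with and without slide 1), 5 with tank number, 8 without the arrays of brightest spike-ins, 15 with slide as a random block, 16 at a threshold of 0.10, 21 with array position, 23 with array weights and 62 with intensity without slide 1.

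Of 168 list and comparison pairs, camera called 22 at first, 11 with quantile scaling, 12 with slide as a block, 52 with normexp, 0 with an estimated correlation and 4 by fry. Some list medians changed sign, several of them along with a shift of all probes that says nothing about the list relative to other genes. The egg envelope had -3.42e-04 at 0.1 and -0.00382 at 10 µg/L in the authors' table, where the median of all probes was -0.08 and -0.27, and 0.10 and 0.21 with its columns centred. Leukocyte genes at 10 µg/L had 0.245 with normexp and 0 with median scaling, where all probes had 0.23 and 0.12, and 0.0796 with the slide block. They had 0.00490 at 100 µg/L in the authors' table (all probes 0.11) and 0.00432 in the mean of exposed groups with median scaling (all probes 0.08). In these fits camera kept the direction of the original fit. Oxidative phosphorylation had -0.0856 at 100 µg/L and -0.00239 per step in the trend with normexp. At 10 µg/L ribosomal proteins kept a positive median in every setting, from 0.12 with quantile scaling to 0.83 with median scaling, and oxidative phosphorylation from 0.08 in the authors' table to 0.80. The egg envelope had 0.07 with quantile scaling (adjusted p = 0.570). The agreement between concentrations was 0.212 with normexp.

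Leaving out 1 array at a time gave 1 to 2583 calls at 10 µg/L, 0 to 1 at 0.01 µg/L, 0 to 10 in the mean of exposed groups, 1 to 2 for the trend, 0 to 7 for the F test, 0 to 18 for gonadosomatic index, 16 to 25 called lists and an agreement of 0.475 to 0.610. Plasma vitellogenin at 10 µg/L differed by -8.22 to -6.05 mg/ml, and the largest difference, without replicate F, had exact adjusted p = 0.0325. No single array removed the ribosomal protein, oxidative phosphorylation or egg envelope calls at 10 µg/L. The leukocyte call at 10 µg/L was lost without replicate A or F of that group or control C (adjusted p up to 0.0917). Hepatocyte genes at 1 µg/L were lost without replicate B, and at 100 µg/L 7 arrays each removed the call. At 100 µg/L oxidative phosphorylation was lost without replicate E or F or control A, at 1 µg/L without C or E, and ribosomal proteins at 0.1 µg/L without control A or replicate B and at 1 µg/L without C, E, control A or control E. The egg envelope was lost at 0.01 µg/L without replicate B, at 0.1 µg/L without control A or replicate B, and in the mean without control A. Leukocyte genes were lost at 0.1 µg/L without replicate B, at 100 µg/L without any of 10 arrays and in the mean without any of 7.

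Groups share replicate letters, but letters did not pair the fish. Of the pairs with control of the same letter, 2 of 5, 2 of 5, 4 of 6, 2 of 6 and 3 of 6 had deviations correlated over 0.1, in order of concentration, and arrays of the same letter on different slides correlated at -0.0105 against 0.262 on the same slide. With the letter as a replicate block 4 probes were called at 10 µg/L, 0 by the F test and 23 lists, and plasma vitellogenin at 10 µg/L kept -6.85 mg/ml, with the smallest exact p that 6 pairs allow (0.0313, adjusted 0.156). Every alternative written before the data were examined was run.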

Other observations

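The genes in this section were chosen after the values had been seen. In the mean of the exposed groups, the ovulation list held opposite movements that its median hid. Over that list alone the prostaglandin synthase ptgs1 was higher (adjusted 0.00104), while the hyaluronan-binding gene tnfaip6 at -0.85 (SE 0.28) and the transcription factor cebpb at -1.16 (SE 0.39), both induced by prostaglandins and gonadotropin in mammals, were lower (each 0.0421). In the cholesterol and lipoprotein list, which shares 1 tested gene with the hepatocyte list, fabp4a was lower (0.00733). At 10 µg/L the same list held a lower sterol sensor insig1 at -0.62 (SE 0.15, 0.00597 over the list) and a higher exporter abcg1 at 0.95, and the peroxide-detoxifying gpx4b was higher at 0.91 (SE 0.23, 0.0172 over its list).

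Cell cycle genes at 10 µg/L moved both ways. The kinase cdk2 was higher at 0.64 (SE 0.15, 0.00672 over the list) with cks2 at 0.86 and the maturation cyclin ccnb1 at 0.68, while the cyclin ccna1 was lower at -1.63 (SE 0.40). Of the apoptosis genes casp2, which acts in oocyte loss in mice, was higher at 1.15 (SE 0.29, 0.0209 over the list) and bmf1 was at -0.86. Without replicate F, which was left out after its values had been seen, further genes passed over all probes, among them the deacetylase hdac8 at 1.19 (SE 0.21, adjusted p = 0.00740), apoeb at -4.52 (SE 0.85, adjusted p = 0.00853), fabp4a at -3.37 (SE 0.87, adjusted p = 0.0189) and grna.2 at -3.29 (SE 0.91, adjusted p = 0.0244). Replicate F itself lay on the other side of control for hdac8 (-0.52), and on the same side for apoeb (-2.74), fabp4a (-2.48) and grna.2 (-2.86). With array intensity as a covariate and slide 1, which holds that array, left out, 0 probes were called at 10 µg/L. Under that fit apoeb stayed at -4.23 (limma adjusted p = 0.203), so the lost call does not show that its change followed intensity.

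Liver tissue in the ovary sample of replicate B at 1 µg/L may account for the called hepatocyte list there. Of 38 tested genes of the hepatocyte and vitellogenin lists, 27 had their highest value of the 34 fish in this array, with a median difference of 3.51 from the other females of its group. The array had been singled out by its hepatocyte list mean, so a high count was likely in advance. The largest were vtg4 at 10.6, vtg5 at 9.93, vtg3 at 9.10, transferrin tfa at 8.37, rbp4 at 7.35 and fga at 6.48. Not raised were, among others, gc at -0.04, apoa1b at -0.48, tdo2b at -0.54 and vtg1 at -1.11. Replicates C and E at 100 µg/L (hepatocyte list means 2.14 and 1.13, vitellogenin list 2.77 and 2.26) and A at 0.1 µg/L (0.90 and 2.46) also had higher levels of these genes and were not tested for liver tissue. Tissue other than liver is not excluded, since the intestine list mean was 0.78 in replicate B at 1 µg/L and 0.86 in replicate C at 100 µg/L (controls at most 0.37), and the leukocyte mean of replicate B was 0.43.

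Lists overlapped little, with 2 genes shared by the ovulation and leukocyte lists and 5 by the steroid synthesis and granulosa lists, and 16 of the 24 phagocyte markers were on the leukocyte list.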
